A study of Mus musculus with 35 samples.

How the data were processed

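The series holds 35 arrays with 2 colours from 12 biological samples of C57BL/6 mouse tissue: 3 of the ganglion cell layer, 3 of the inner nuclear layer, 3 of the wild-type photoreceptor layer, 2 of the Nrl null photoreceptor layer and 1 of the retinal pigmented epithelium. Per the labels, about 15 ng of total RNA from captured tissue was amplified in 2 rounds of in vitro transcription and labelled with Cy5, and 2 µg of adult retina RNA was amplified in 1 round and labelled with Cy3. Dyes were never swapped. The labels describe replicate 3 of the 3 wild-type layers as a pool, and each biological sample was hybridised on 3 arrays, except PR Nrl null replicate 1, which has 2.

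The deposited scanner files hold the intensity of each spot and of its local background on a linear scale, 1 file per channel and array, 70 in all, before any normalization. Per the file headers, spots were measured with a fixed circle and tested for emptiness; the meaning of the flag codes is not given in the sources used here. The authors' value table of the series holds values for 6524 of the 34992 spots. How the authors normalized it is not given in the sources used here. Set against the scanner ratios over bright unsaturated spots, its columns had slopes of 0.898 to 1.03 and correlations of 0.520 to 0.996, the lowest in PR WT replicate 3 array 2. Its direction (Cy5 over Cy3) and log2 scale were taken from this, for bright spots only. Its values ranged from -43.0 to 90.5, and 149 of 217160, on 22 arrays, lay beyond 16 in size, more than log2 ratios of 16 bit scans can reach; what they hold is not given in the sources used here, and they were kept where the table was used. Column medians ranged from -0.97 to 0.43, and the centring behind them stays unknown. All of its columns matched a sample by name.

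Spot intensities were read with Python 3.11.15 and analysed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 and each array was normalized by loess, in which control and empty spots had weight 0. Spots with flag code 1 were left out on their array. Spots of the same probe were averaged. A probe was kept if its signal exceeded the local background by 2 background SDs on at least a share of 0.5 of the arrays of any group in Cy5, or of all arrays in Cy3. This left 7080 of 34215 probes. Different probes of the same gene were represented by the brightest, which left 7054 genes and unnamed probes. Arrays of the same biological sample were averaged before testing. No pair of arrays held identical values.

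Probe names include 19 accessions, of which 17 matched a symbol in the gene table given, without versions. All other probes have identifiers of the array design that the files do not pair with genes. Of 26 gene lists (500 distinct members) fixed before the data were examined, 4 had a measured member: Müller glia (Vim), glycolysis (Gapdh), lysosome (Ctsd) and ribosomal protein (Rpl13a). The lists of rod, cone and shared photoreceptor, ganglion, amacrine, bipolar, horizontal, astrocyte, vascular, microglial, pigmented epithelial, pigmentation, choroid, lens, blood, stress, oxidative phosphorylation, cilium, receptor, channel and myelin genes had no measured member. No list reached the 4 members set for a list test, and camera was not run.

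The rule for named genes, fixed before the data were examined, was Nrl first, then the 10 largest increases and 10 largest decreases among genes with a symbol that passed without overlap between samples, up to 4 members of each list, and single genes set by name, among them Opn1sw and Opn1mw. With 14 named genes measured, any of them may be described, which goes beyond the rule. Some genes are not reported here. Unnamed probes are described by the largest difference in each direction, and identifiers are printed only for 2 raised and 2 lowered probes of the Nrl null comparison.

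limma's lmFit and eBayes were fitted over all 12 samples with a coefficient per group (residual df 7, prior df 8.93), and p-values are two-sided and adjusted by Benjamini-Hochberg over all genes and probes tested, with calls at an adjusted p under 0.05. A gene was layer-enriched if it passed and was higher in both contrasts against the other wild-type layers. Where the dim group was never above background, a fold is given as a bound. The bound sets the bright group's mean Cy5 signal, after loess and Aquantile, against the higher of the dim probe's own signal and the lowest signal among probes above background on each dim array; it is open to dye bias, as no dyes were swapped, and is not given where it exceeds the fold of the log2 ratios. Shares higher in a group were compared over alternatives with at least 5 calls. Shared controls were simulated with 100 data sets. On simulated data with 200 changed genes among 7054, changes of log2 2 were recovered in 83.6% for GCL against PR WT, 80.6% for INL against PR WT, 88.1% for GCL against INL, 82.1% for PR Nrl null and 43.3% for RPE, and changes of log2 1 in 2.98%, 8.96%, 11.9%, 8.96% and 4.48%.

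Array print runs came from the file names. Run 12 held GCL and INL replicates 1 and 2, PR WT replicate 1 and RPE. Run 13 held the other samples. Scan dates in the headers form 4 sessions with gaps of more than 10 days; session 4 held GCL, INL and PR WT replicate 3 and both PR Nrl null samples. Alternatives planned before the data were examined were no background correction, an offset of 0, median centring, scale normalization between arrays, the Cy5 channel alone, no filter, a stricter filter (a share of 0.75 of the arrays of every group), flags ignored, all arrays with the sample as a random block, print run as a block or alone, the replicate number as a block, only the groups compared, trended and robust eBayes, other probe rules, the authors' value table, a minimum log2 fold change of 1 and leaving out each sample. The scanning session as a block, session 4 alone and sample quality weights were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.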

Results

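Gene expression was measured in layers of the adult mouse retina and in the retinal pigmented epithelium, each isolated from sections by laser capture microdissection. The ganglion cell layer (GCL), the inner nuclear layer (INL) and the wild-type photoreceptor layer (PR WT) were each represented by 3 biological samples. The photoreceptor layer of Nrl null mice (PR Nrl null) had 2 and the retinal pigmented epithelium (RPE) had 1. Nrl encodes a transcription factor needed for rod photoreceptor fate. All mice were 3 months old. Each sample was labelled with Cy5 and hybridised on 2 or 3 spotted oligonucleotide arrays, 35 in all, together with whole adult retina RNA labelled with Cy3. Values are log2 ratios of layer RNA over this retina reference after loess on each array. A value of 0 is therefore the usual ratio of probes of similar intensity, not the level of whole retina. The labels call the samples biological replicates without tying them to animals, and p-values therefore measure the spread between these samples. They also describe replicate 3 of each wild-type layer as a pool without saying of what; if it pooled the other replicates, the 3 samples would not be independent, and their SDs, SEs and p-values would be too small. The small number of arrays limits the precision of every value.

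The share of probes above background in the layer RNA ranged from 7.89% in PR WT replicate 2 to 17.6% in INL replicate 2. GCL samples correlated with each other across probes at r = 0.718 to 0.874, INL samples at 0.640 to 0.803 and PR WT samples at 0.562 to 0.656. The 2 PR Nrl null samples correlated at 0.689. Between layers, GCL and INL samples correlated at 0.548 to 0.824 and GCL and PR WT samples at 0.245 to 0.581. INL and PR WT samples correlated at 0.242 to 0.700, and PR Nrl null and PR WT samples at 0.310 to 0.560. The value of 0.700 came from INL replicate 1 and PR WT replicate 1, which shared a print run and a scanning session. It lay above every pair of PR WT samples. The RPE sample correlated with GCL at 0.498 to 0.708, with INL at 0.479 to 0.703, with PR WT at 0.427 to 0.588 and with PR Nrl null at 0.271 to 0.428. GCL replicates 1 and 2, which shared its print run and scanning session, gave 0.701 and 0.708, and GCL replicate 3 gave 0.498. The PR Nrl null samples shared neither with RPE, so these values mix tissue with print run and session. Probes are not independent replicates, and these coefficients describe the samples only. Arrays of the same biological sample correlated least in PR WT replicate 2, where the lowest pair reached 0.422.

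**Figure D1:**
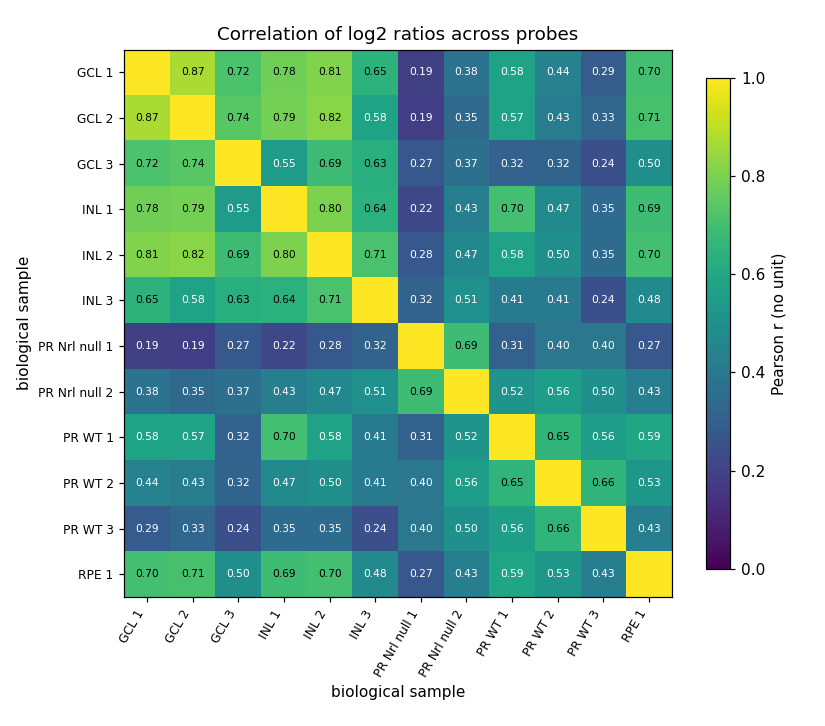
Pearson r of log2 ratios across 7054 genes and unnamed probes (no unit; colour and printed value) for each pair of the 12 biological samples on both axes. GCL and INL samples correlate with each other at up to 0.824, while PR Nrl null and GCL samples reach at most 0.382.

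The measured set comprised 7054 genes and unnamed probes. Of these, 14 carried a gene symbol, nearly all of them genes with general cellular roles, among them Actb, B2m, Ctsd, Eef2, Gapdh, Gsn, Hprt, Lrp1, Rpl13a, Rpn2, Tln1, Vim and Ywhaz. The remaining probes carry only identifiers of the array design, which the files do not pair with genes. Nrl itself and the cone opsins Opn1sw and Opn1mw were therefore not analysed here, and the genotype of the PR Nrl null samples was not checked against Nrl expression. On this scale Lrp1, a lipoprotein receptor, was the highest of the 14 genes in GCL (1.24 ± 0.10, SD, n = 3), INL (1.34 ± 0.34, n = 3) and PR WT (1.18 ± 0.24, n = 3). Vim, an intermediate filament gene of Müller glia and other cells, lay at -2.70 ± 0.19 in GCL at its brightest probe. Its other probes lay at -2.43 and 0.16 in GCL. Such distances from the reference mix tissue differences with dye and amplification, because layer RNA always carried Cy5 after 2 rounds of amplification and reference RNA always carried Cy3 after 1. Per the labels every layer sample was treated alike in this respect, and the comparisons below set layer samples against each other. Amplification effects need not cancel between them, since the excess of the 3' segment of Vim over its other segments was 2.73 in GCL, 3.19 in INL, 1.69 in PR WT and 3.47 in RPE.

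**Figure D2:**
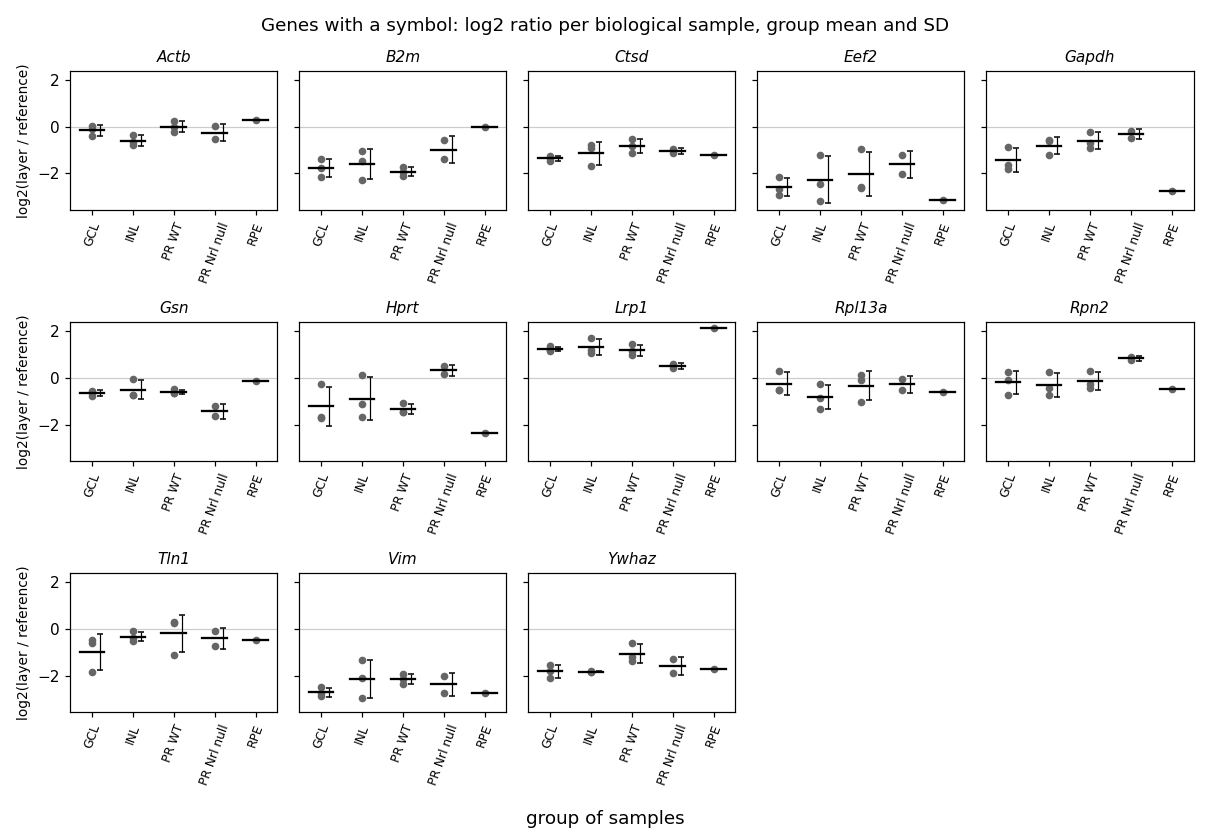
Log2 ratio of layer RNA over the retina reference (vertical axis, log2 units) in each biological sample (points) of the 5 groups (horizontal axis) for 13 of the genes with a symbol. Horizontal lines are group means and error bars 1 SD, with no SD for the single RPE sample; Gapdh in RPE lies at -2.77 and Hprt in PR Nrl null at 0.32.

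The first comparison asked which transcripts separate the inner from the outer neuronal layers. GCL and PR WT differed at 726 of 7054 genes and unnamed probes, of which 418 were higher in GCL and 308 higher in PR WT. The median size of these differences was 1.83 on the log2 scale. The unnamed probe with the largest excess in GCL differed by 4.76 (SE 0.46, limma adjusted p = 6.43e-06). That probe was not well above background on any of the 9 PR WT arrays, so the size of its excess is only a bound. The unnamed probe with the largest excess in PR WT differed by -6.03 (SE 0.55, limma adjusted p = 3.72e-06), with -4.65 ± 0.62 in GCL and 1.38 ± 1.34 in PR WT (SD, n = 3 each).

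None of the 14 named genes passed between GCL and PR WT. Gapdh, the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, differed by -0.83 (SE 0.36, limma adjusted p = 0.184), and all 4 of its probes had the same sign. As the only measured member of the glycolysis list, Gapdh had a limma adjusted p = 0.0373 when adjusted over the list alone, but its difference turned to 0.28 after median centring and to 1.80 in the Cy5 channel alone (adjusted p = 0.981 and 0.539). With sample quality weights it was -1.10 (adjusted p = 0.0280), the 1 of 26 alternatives in which it passed. Ywhaz, which encodes a 14-3-3 protein, differed by -0.75 (SE 0.34, limma adjusted p = 0.190), with every GCL sample below every PR WT sample. For Ctsd, the lysosomal protease cathepsin D, the difference was -0.53 (SE 0.34, limma adjusted p = 0.376). Vim differed by -0.56 (SE 0.40, limma adjusted p = 0.426), with 1 of its 3 probes of the opposite sign, and Rpl13a, a ribosomal protein gene, by 0.08 (SE 0.41, limma adjusted p = 0.927).

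The GCL and PR WT counts came from a limma model over all 12 samples, and 1631 genes and probes had an unadjusted p under 0.05. In 297 of the 726 differences the dimmer layer was never above background, so only a bound on the fold is known. GCL and PR WT samples shared 2 print runs of the array: with print run as a block 958 genes and probes passed, with 265 within print run 12 and 367 within print run 13. With the scanning session as a block 463 passed. Print run 12 held 1 PR WT sample, print run 13 held 1 GCL and 1 INL sample, and session 4 held 1 sample of each wild-type layer. Counts within them therefore take the spread of a layer with 1 sample from other groups. The share higher in GCL was 57.6% and ranged over 28 alternatives from 22.5% of 138 under a stricter filter on signal to 78.8% of 358 after median centring. The majority turned in 4 of them, among them the fit without PR WT replicate 1 (43.8% of 785).

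INL and PR WT differed at 443 genes and unnamed probes, 261 higher in INL and 182 higher in PR WT, with a median size of 1.83. The unnamed probe with the largest INL excess lay at 1.68 ± 0.73 in INL and -2.61 ± 0.32 in PR WT (SD, n = 3 each), a difference of 4.29 (SE 0.41, limma adjusted p = 3.56e-05). The probe that led the GCL excess over PR WT was second here, at 4.14 (SE 0.46, limma adjusted p = 7.56e-05), at least 17.3-fold. The probe lowest in GCL relative to PR WT was also the lowest in INL, at -4.80 (SE 0.55, limma adjusted p = 7.56e-05). Among named genes, Ywhaz differed by -0.77 (SE 0.34, limma adjusted p = 0.222), and every INL sample lay below every PR WT sample. Actb, cytoplasmic beta-actin, differed by -0.60 (SE 0.33, limma adjusted p = 0.346) and Vim by 0.00 (SE 0.40, limma adjusted p = 0.998) at its brightest probe, while 1 of its 3 probes passed on its own at 1.46 (limma adjusted p = 0.0415). That probe was the dimmest of the 3 and the 3' segment, whose excess over the other segments was 3.19 in INL and 1.69 in PR WT. Control spots with its reverse complement were above background in 50% of INL and 0 of PR WT readings. A gain of Vim in INL cannot be told apart from these effects.

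GCL and INL departed from PR WT at many of the same genes. Of the genes and probes that passed in both comparisons, 170 were higher in GCL and INL alike and 150 were lower in both, against 15.5 and 7.95 for independent lists, and 0 went opposite ways. The GCL and INL differences from PR WT had a covariance of 0.540 across genes, where unchanged groups set against the same PR WT samples gave 0.0864 in simulation, and r was 0.803 against 0.498. With 3 PR WT samples the controls were not split, and part of the excess may come from those shared samples.

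In INL against PR WT, 1360 genes and probes had an unadjusted p under 0.05, and in 151 of the 443 differences the dimmer layer was never above background. The INL count was 668 with print run as a block, 106 within print run 12 and 153 within print run 13, 445 with the scanning session as a block and 0 within the session that held 4 of the groups (926 at an unadjusted p under 0.05 in limma), where each wild-type layer had 1 sample. Leaving out INL replicate 2 gave 243, PR WT replicate 2 gave 292 and PR WT replicate 3 gave 273. The share higher in INL was 58.9% and ranged over 27 alternatives from 37.6% of 93 under the stricter filter to 76.7% of 374 from the Cy5 channel alone, and the majority turned in 2, the stricter filter and the fit without PR WT replicate 1 (42.3% of 504).

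GCL and INL differed at 61 genes and unnamed probes. Of these, 23 were higher in GCL and 38 higher in INL, with a median size of 2.13. The unnamed probe with the largest GCL excess differed by 3.79 (SE 0.45, limma adjusted p = 0.000702), at least 12.9-fold, since none of the 9 INL arrays showed it well above background. The unnamed probe with the largest INL excess differed by -3.41 (SE 0.43, limma adjusted p = 0.000912). Gapdh differed by -0.63 (SE 0.36, limma adjusted p = 0.738), Rpl13a by 0.57 (SE 0.41, limma adjusted p = 0.834) and Vim by -0.56 (SE 0.40, limma adjusted p = 0.833).

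For GCL against INL, 582 genes and probes had an unadjusted p under 0.05 in limma, and in 16 of the 61 differences the dimmer layer was never above background. The GCL and INL count was 122 with print run as a block, 8 within print run 12 and 0 within print run 13, where each of the 2 layers had 1 sample (519 at an unadjusted p under 0.05), 87 with the scanning session as a block and 0 within the session that held 4 of the groups, again with 1 sample each (459 unadjusted). Without GCL replicate 1 it was 33, without GCL replicate 2 it was 27 and without INL replicate 3 it was 35. The share higher in GCL was 37.7% and ranged over 26 alternatives from 4.76% of 21 under the stricter filter to 66.7% of 9 after median centring, and the majority turned in 2.

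Across the 3 wild-type layers, limma's F test passed 715 genes and unnamed probes. Genes higher in 1 layer than in both of the others numbered 22 for GCL, 22 for INL and 150 for PR WT. The 150 PR-enriched genes and probes had a median log2 ratio of 0.37 in PR WT, -1.76 in INL and -2.11 in GCL. GCL-enriched probes had medians of 1.55 in GCL, -0.50 in INL and -0.50 in PR WT, and INL-enriched probes 1.04 in INL, -0.91 in GCL and -0.94 in PR WT. The PR WT set held 96 without INL replicate 2, 233 without PR WT replicate 1, 83 without PR WT replicate 2 and 92 without PR WT replicate 3. The GCL set fell to 13, 10 and 13 without GCL replicates 1, 2 and 3 and to 11 without INL replicate 1, and the INL set to 12 without either of GCL replicates 1 and 2 and to 14 without either of INL replicates 2 and 3. With print run as a block the sets held 45 for GCL, 36 for INL and 167 for PR WT, and with the scanning session as a block 21, 28 and 113. Within print run 12 the 3 sets held 2, 1 and 34, and within print run 13, with 1 GCL and 1 INL sample, they held 0, 0 and 42.

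**Figure D3:**
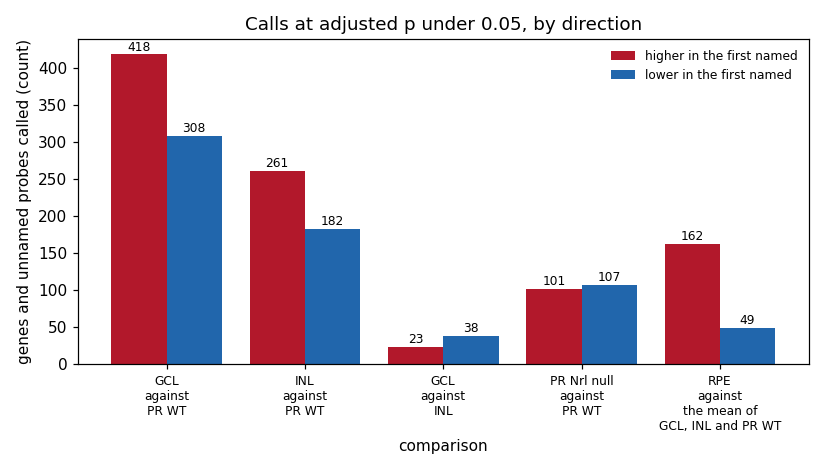
Number of genes and unnamed probes (vertical axis, count) with a limma adjusted p under 0.05 in each comparison (horizontal axis), with red bars for those higher and blue bars for those lower in the group named first. GCL against PR WT has 418 higher and 308 lower, and GCL against INL has 23 higher and 38 lower.

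The PR Nrl null comparison asked what changes in the photoreceptor layer when Nrl is lost. PR Nrl null and PR WT samples differed at 208 of 7053 genes and unnamed probes, 101 higher and 107 lower in the null. The unnamed probe scl35175.1.186_300 rose by 3.64 (SE 0.49, limma adjusted p = 0.00137), from -0.57 ± 0.61 in PR WT (SD, n = 3) to 3.07 ± 0.16 in the null (n = 2), and was above background on 5 of 5 null arrays and 1 of 9 PR WT arrays. It was also higher than in PR WT in GCL, by 1.78 (limma adjusted p = 0.0137), and in INL, by 1.82 (limma adjusted p = 0.0183), each in 16 of 25 alternatives (adjusted p up to 0.201 and 0.288). The unnamed probe scl52114.2_187 rose by 3.64 (SE 0.55, limma adjusted p = 0.00221), from 0.25 ± 0.66 to 3.89 ± 0.66. In GCL and INL scl52114.2_187 lay at 0.39 and 0.33. The largest decrease was that of scl018185.1_8, which changed by -5.31 (SE 0.49, limma adjusted p = 7.31e-05), and scl34459.22.1_92 followed at -4.35 (SE 0.54, limma adjusted p = 0.000851). Both of these lowered probes were also far below PR WT in GCL, by -5.83 and -5.31, and in INL, by -4.26 and -3.60.

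No named gene passed between PR Nrl null and PR WT. Hprt, a purine salvage enzyme gene, differed by 1.65 (SE 0.53, limma adjusted p = 0.114), with both null samples above every PR WT sample. Rpn2, which encodes a subunit of the oligosaccharyltransferase complex, differed by 0.95 (SE 0.42, limma adjusted p = 0.276), with 4 of its 6 probes of that sign. B2m, the light chain of MHC class I, differed by 0.94 (SE 0.43, limma adjusted p = 0.294). Gsn, the actin-severing protein gelsolin, differed by -0.83 (SE 0.37, limma adjusted p = 0.274). Reverse complement control spots of Hprt were above background in 80% of null and 11.1% of PR WT readings. For Rpn2 the shares were 60% and 11.1%, for Gsn 0 and 33.3%, and for B2m 0 in both. Differences of Hprt, Rpn2 and Gsn go the same way as this signal and cannot be told apart from it. The list members Gapdh (0.29, limma adjusted p = 0.770), Vim (-0.23, limma adjusted p = 0.845), Ctsd (-0.22, limma adjusted p = 0.820) and Rpl13a (0.05, limma adjusted p = 0.971) did not pass either.

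Of the 150 PR-enriched genes and probes, 93 lay below PR WT in the PR Nrl null samples, with a median change of -0.40. In the limma test 25 were lower and 4 higher, and their median log2 ratio in the null was -0.03. Of all genes and probes, 46.3% lay below PR WT. So did 18 of the 22 GCL-enriched (median change -0.53) and 8 of the 22 INL-enriched (median change 0.41), so lower values were not particular to the PR-enriched set. The PR-enriched set was chosen on the same PR WT samples, which favours lower values in the null. Genes changed in the null overlapped those that separate GCL from PR WT, with 30 higher and 27 lower in both against 5.99 and 4.67 for independent lists, and 12 went opposite ways. For INL the overlap was 21 higher and 29 lower against 3.74 and 2.76, and 4 were opposite. The covariance of null and GCL differences from PR WT was 0.117 against 0.0862 with no effect in simulation, and that of null and INL differences 0.142 against 0.0864; the correlations were 0.178 and 0.249 against 0.445 and 0.446. The correlations thus lay below those with no effect and the covariances above them, so these values do not settle whether the null resembles GCL or INL beyond the shared samples. The PR WT samples were not split, and part of the overlap may come from sharing them.

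In the PR Nrl null comparison, 1136 genes and probes had an unadjusted p under 0.05, and in 107 of the 208 differences the dimmer group was never above background. The null samples were all on print run 13: 315 passed with print run as a block and 97 within print run 13, 121 with the scanning session as a block and 1 within the session that held both null samples and 1 PR WT sample. The count was 56 and 68 without PR Nrl null replicates 1 and 2, where the remaining null sample is assumed to vary like the other groups, and 97 and 91 without PR WT replicates 2 and 3. The share higher in the null was 48.6% and ranged over 25 alternatives from 35.7% of 370 from the Cy5 channel alone to 81.5% of 27 after median centring, with a majority higher in 13. Scale normalization left scl52114.2_187 at 2.84 (limma adjusted p = 0.0510) and scl34459.22.1_92 at -3.58 (0.0530), and the authors' value table left scl52114.2_187 at 4.33 (0.0781). Within the session that held both null samples, adjusted p was 0.111 for scl35175.1.186_300, 0.151 for scl52114.2_187, 0.111 for scl34459.22.1_92 and 0.0407 for scl018185.1_8, in a fit with 1 residual df, while their differences stayed at 3.31, 2.94, -4.47 and -5.74. With the session as a block all 4 passed, at 3.17, 2.76, -4.38 and -5.71. Over all alternatives run, scl018185.1_8 passed in 25 of 25, scl35175.1.186_300 in 22 of 23, scl34459.22.1_92 in 22 of 24 and scl52114.2_187 in 21 of 24. The lowest limma adjusted p of scl018185.1_8 (8.6e-11) and scl52114.2_187 (2.08e-07) came from all arrays with the sample as a random block. Arrays of the same sample count there as partly independent. Those of scl35175.1.186_300 (3.46e-06) and scl34459.22.1_92 (5.54e-07) came from the replicate block, whose numbers are not known to pair samples. None of these is stronger evidence than the p-values from the fit over all 12 samples.

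The RPE, the pigmented cell layer behind the photoreceptors, was compared with the mean of GCL, INL and PR WT. With 1 RPE sample the test takes its spread from the other groups, so it cannot separate the tissue from that sample. RPE differed at 211 genes and unnamed probes, 162 higher and 49 lower, with a median size of 2.32. The unnamed probe with the largest RPE excess differed by 4.97 (SE 0.84, limma adjusted p = 0.00363). The next differed by 4.73 (SE 0.40, limma adjusted p = 1.92e-05), and because it was not well above background on any of the 27 arrays of the layers, the size of its excess is only a bound. The largest decrease in RPE was -3.33 (SE 0.50, limma adjusted p = 0.00169).

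Gapdh was the only named gene that passed in RPE, where the 1 sample has no spread of its own. It fell by 1.82 on the log2 scale (SE 0.47, limma adjusted p = 0.0469), and the RPE sample, at -2.77, lay below every GCL, INL and PR WT sample. All 4 Gapdh probes had this sign, at -1.82 for the brightest, which stands for the gene, and at -0.76, -1.48 and -1.22 for the others. The brightest probe is the 3' segment. Its excess over the other segments was 1.015 in RPE, against 1.82 in GCL, 1.86 in INL and 1.46 in PR WT (0.27 to 2.09 over PR WT samples). Whether this shaped the RPE difference was not tested. The Gapdh call ended without GCL replicate 1 (limma adjusted p = 0.0562), GCL replicate 2 (0.0604), INL replicate 2 (0.0683), INL replicate 3 (0.0598), PR WT replicate 2 (0.0709) or PR WT replicate 3 (0.0504), with differences that stayed between -1.88 and -1.75. Gapdh differed by -0.30 after median centring (adjusted p = 0.999) and by -0.13 in the Cy5 channel alone (adjusted p = 0.981). Over 27 alternatives the Gapdh call held in 7, with adjusted p from 0.0232 to 0.999. B2m differed by 1.74 in RPE (SE 0.50, limma adjusted p = 0.0748), with the RPE sample above every layer sample. B2m passed with print run as a block, where the difference was 1.96 (limma adjusted p = 0.0220), and in 6 of 26 alternatives in all, with adjusted p from 0.00787 to 0.321. Hprt differed by -1.20 (SE 0.61, limma adjusted p = 0.358) and Lrp1 by 0.88 (SE 0.41, limma adjusted p = 0.312). Vim (-0.39, limma adjusted p = 0.786), Ctsd (-0.12, limma adjusted p = 0.940) and Rpl13a (-0.13, limma adjusted p = 0.949) did not pass either.

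RPE had 1 biological sample on 3 arrays, and limma's test assumes that it varies like the other groups. For RPE, 1132 genes and probes had an unadjusted p under 0.05, and in 64 of the 211 differences the dimmer side was never above background. The RPE count was 328 with print run as a block and 286 within print run 12, and 171 with the scanning session as a block. The share higher in RPE was 76.8% and ranged over 29 alternatives from 35.3% of 17 under the stricter filter to 98.0% of 50 after median centring, and the majority turned in 2, the stricter filter and the authors' value table (46.8% of 94). Median centring moved the median difference of all genes by 0.39 in GCL against PR WT, 0.28 in GCL against INL, 0.36 in PR Nrl null against PR WT and 0.16 in RPE. The Cy5 channel alone moved it by 0.24 in GCL, 0.18 in INL and 0.17 in PR Nrl null, each against PR WT, and the authors' value table by 0.28, 0.23 and 0.19.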

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

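All values in this part were looked at after the arrays had been normalized, and none of them was explained by a test. Single arrays far from the others of their group were sought in 64 combinations of group and measure, over the shares of probes above background and the 14 named genes, and 6 were found; chance alone gives about 1 in 20 for independent values, which arrays of the same sample are not. Vim lay at -1.97 on GCL replicate 1 array 3, with the next of the 9 GCL arrays at -2.58 and the farthest at -3.00. Rpl13a lay at -2.06 on INL replicate 1 array 2, with the next INL array at -1.09. Rpl13a lay at 0.31 on PR Nrl null replicate 1 array 1, with the next of 5 null arrays at -0.38. The 3 others were arrays of PR WT replicate 2, the sample whose arrays correlated least with each other: B2m at -0.44 on array 3 (next PR WT array -1.74), Vim at -3.18 on array 1 (next -2.25) and Gapdh at 0.77 on array 1 (next -0.61).

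Control spots that carry the reverse complement of a gene's probe, which no comparison used, gave Cy5 signal for some genes. The share of array readings above background was 41.4% for Gsn, 31.4% for Hprt, 20.0% for Rpn2 and 17.1% for Vim, where spots of random sequence reached at most 13.5% on any array and 3.76% over all arrays. The reverse complement of Gsn was above background in 83.3% of readings in RPE, 55.6% in INL, 44.4% in GCL, 33.3% in PR WT and 0 in PR Nrl null. That of Hprt was above background in 80.0% in PR Nrl null, 66.7% in INL and 11.1% in PR WT, and in 0 in GCL and RPE. That of Rpn2 reached 60% in PR Nrl null and 33.3% in INL, and that of Vim 50% in INL and 50% in RPE. The reverse complements of B2m, Rpl13a, Tbp and Tln1 gave 0 in Cy5.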

How the results depend on the processing

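The fits with the scanning session as a block, within session 4 and with sample quality weights were chosen after seeing the data. Counts are of genes and unnamed probes, and the cause of a change was not tested unless stated. No gene with a symbol passed with opposite signs, but 176 of 1766 values of such genes under alternatives, none past the threshold, had the opposite sign, and the majority direction of calls turned under some alternatives in every comparison. Trended and robust eBayes, every probe tested, the mean of a gene's probes, flags ignored and a minimum log2 fold change of 1 (not applied to the F test) left every count within 1.5 times. Without background correction, GCL against INL had 105 and the GCL-enriched set 52; with an offset of 0 that set had 14. Median centring gave 358 for GCL against PR WT, 125 for INL against PR WT, 9 for GCL against INL, 27 for PR Nrl null, 50 for RPE, 262 for the F test and 6, 1 and 44 for the GCL-, INL- and PR-enriched sets. Scale normalization gave 39 for GCL against INL, 16 for PR Nrl null and 324 for RPE. The Cy5 channel alone gave 21 for GCL against INL, 370 for PR Nrl null, 107 for RPE and 9, 11 and 79 for the enriched sets. Without a filter, RPE had 124. Under the stricter filter, which left 1206 genes and probes, counts were 138, 93, 21, 37 and 17 in the order above, 142 for the F test and 1, 7 and 49 for the enriched sets. With all arrays and the sample as a random block, INL against PR WT had 694, GCL against INL 156, PR Nrl null 382, RPE 374 and the enriched sets 53, 45 and 263. With print run as a block, INL against PR WT had 668, GCL against INL 122, PR Nrl null 315, RPE 328 and the GCL- and INL-enriched sets 45 and 36; 720 of the 726 GCL against PR WT calls and all 443, 61, 208 and 211 of the others were kept. With fewer samples, print run 12 alone gave 265, 106 and 8 for the 3 pairs of layers, 203 for the F test and 2, 1 and 34 for the enriched sets, and print run 13 alone gave 367, 153 and 0, 97 for PR Nrl null, 302 for the F test and 0, 0 and 42. Replicate numbers are shared between groups: with the replicate block, INL against PR WT had 704, GCL against INL 113, RPE 363 and the enriched sets 54, 43 and 238, and PR Nrl null had 185. Deviations of samples with the same number correlated at -0.163 to 0.443 (mean 0.108), and 7 of 9 layer samples correlated best with a sample of their own number, but numbers overlap with print runs, and samples of the same run correlated at a mean of 0.128 against -0.112 between runs. With only the groups compared, PR Nrl null had 98. The authors' value table, with 5606 genes and probes, gave 433, 275, 7, 34 and 94, 366 for the F test and 1, 3 and 76 for the enriched sets. With the session as a block, GCL against PR WT had 463 and PR Nrl null 121, and 424 of 726, 349 of 443, 54 of 61, 100 of 208 and 135 of 211 calls were kept, all with the same sign. Session 4 alone, with fewer samples, gave 97 for GCL against PR WT, 0 for INL against PR WT, 0 for GCL against INL, 1 for PR Nrl null, 19 for the F test and 0 for each enriched set. With sample quality weights, GCL against PR WT had 1240, GCL against INL 131, RPE 346 and the enriched sets 45, 43 and 270. Leaving out each sample in turn gave 524 to 785 for GCL against PR WT, 243 to 504 for INL against PR WT, 27 to 48 for GCL against INL, 56 to 194 for PR Nrl null, 147 to 236 for RPE, 494 to 716 for the F test, 10 to 23 for the GCL-enriched, 12 to 22 for the INL-enriched and 83 to 233 for the PR-enriched set. Of the values of named genes under alternatives, 15 passed where the value from all 12 samples did not and 20, all of Gapdh in RPE, no longer passed, at adjusted p of 0.0504 to 0.999. Among the 15 were Ywhaz in GCL and in INL against PR WT and Hprt in PR Nrl null. Each passed with all arrays and the sample as a random block (limma adjusted p = 0.0347, 0.0426 and 0.00394). The Hprt difference cannot be told apart from the signal of its reverse complement control spots. The list test with an estimated correlation was not run, since no list had enough members. Signal over background limits the dim side: 297 of 726, 151 of 443, 16 of 61, 107 of 208 and 64 of 211 differences have only a bound.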

Other observations

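The tests of the tiled genes, of the scanning session in the PR Nrl null comparison and for INL against PR WT, of the GCL- and INL-enriched sets with PR WT kept together, and of PR-enriched genes in PR Nrl null against GCL and INL, were chosen after the result was seen. PR Nrl null differed from INL at 623 genes and unnamed probes in limma, 279 higher in the null, and from GCL at 989, 506 higher in the null. Of the 150 PR-enriched genes and probes, 81 were higher in PR Nrl null than in INL, 94 higher than in GCL and 79 higher than in both, and 0 were lower than in either. The PR-enriched set was chosen partly on the same GCL and INL samples, which favours that direction. In RPE the median of the PR-enriched set was -1.56, that of the GCL-enriched set -0.35 and that of the INL-enriched set -1.13.

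PR WT samples lay further from GCL and from INL than GCL from INL. Lower signal in the PR WT samples as the whole cause is argued against by probes above background in every group. Among them the mean of 138 and 93 differences from PR WT was 5.50 times the 21 between GCL and INL. Among all probes tested the counts were 726, 443 and 61. Counts of calls are not distances, and lower signal as part of the cause stays open. With the scanning session as a block, the root mean square difference of GCL from PR WT was 1.65 times that of GCL from INL. The ratio was at least 1.33 with any of the 9 samples left out. For INL it was 1.41 and fell to 0.998 with 1 of the samples left out. These sizes include estimation noise, which the block raises most for PR WT, as its replicate 2 was alone in its session. A ratio above 1 can therefore come from noise, and the session stays open for both layers. A difference between the layers themselves may underlie the distance of PR WT, as a hypothesis. Carry-over of neighbouring tissue during capture and the length of the amplified RNA were not tested.

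For the F test over the 3 wild-type layers, 715 genes and probes passed in the real grouping. The others of 100 drawn splits of the 9 samples gave at most 571. Those that kept the 3 PR WT samples together and mixed GCL with INL gave 571, 432 and 427, and the rest at most 32. The F test count thus rests largely on PR WT against the other layers. Only 1 split, the real one, gave as many, a share under 0.05. The splits moved samples freely across replicate numbers, print runs and sessions, so the share holds only if these do not matter. For the 150 PR-enriched genes, 3 of 100 splits, the real one included, held as many in any group. The same limit applies, and this share does not exclude chance. The higher counts were 161 and 156. Both splits kept the 3 PR WT samples together and mixed GCL with INL, which points to PR WT standing apart from both. For the 22 GCL-enriched and the 22 INL-enriched genes, the 6 samples of these layers were split with PR WT kept together: 1 of 10 splits, the real one, held as many and the others 0, but 10 splits are too few for a share under 0.05. For each pair of layers only 1 of 10 splits, the real one, gave as many, but 10 splits are too few for a share under 0.05: the real counts were 726, 443 and 61 and the highest others 0 for GCL against PR WT, 0 for INL against PR WT and 1 for GCL against INL.

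PR Nrl null samples all came from print run 13, while PR WT replicate 1 came from print run 12. If print run were the cause, the difference between runs within GCL and INL would exceed the null change, because PR WT replicates 2 and 3 shared run 13 with the null samples. Over the 208 genes and probes the median run difference was 0.125 times the null change, with quartiles of -0.004 and 0.297. In GCL and INL that run difference is also the difference of replicate 3 from replicates 1 and 2. With the scanning session as a block, the null change kept a median of 0.954 times its size (quartiles 0.886 and 1.05). Of the 208, 100 still passed, with 4 residual df in place of 7. Cells of the inner nuclear layer in the null samples would bring levels between PR WT and INL, yet 56.4% of the 101 raised genes were higher in the null than in INL, and 38.3% of the 107 lowered genes were lower in the null than in INL. These tests argue against print run or scanning session as the whole cause and against inner nuclear layer cells for those genes, not for the rest, although genes chosen on the same null samples lean towards such extremes. Loss of Nrl may account for the changes, as a hypothesis, while cells of other layers stay open.

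The genes tiled with a probe per exon segment had higher layer over reference ratios at their 3' end. The last measured segment exceeded the mean of the others in at least 10 of 12 samples for 5 of 7 genes, by 2.54 ± 0.76 in Vim (SD over 12 samples), 1.84 ± 0.57 in Actb, 1.53 ± 0.75 in Gapdh, 0.92 ± 0.57 in Rpn2 and 0.69 ± 0.54 in Tln1. For Ctsd the value was -0.11 ± 0.53 and for Eef2 -0.31 ± 0.66. For Vim it was 1.31 to 1.95 in PR WT samples, 2.55 to 3.06 in GCL and 2.54 to 3.82 in INL, and for Actb 1.33 to 1.90 in PR WT, 1.99 to 2.72 in GCL and 1.07 to 1.81 in INL, while for Gapdh, Rpn2 and Tln1 the samples of these layers overlapped. Shorter RNA after the second amplification round of the layer samples may explain the 5 genes; dye and probe effects were not separated from it, and no biological explanation was tested.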
